A study of Homo sapiens with 18 samples.

How the data were processed

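Biotin-labelled cRNA made from total RNA of the endometrial cancer cell lines Hec-1A and RL95-2 was measured on Illumina bead arrays, 18 arrays in 6 groups of 3. The groups were set by the cell line and the treatment in the labels, which were control IgG, PDGF-AA, or PDGF-AA + 3G3. Dose and duration of treatment are not given in the sources used here. The labels do not say that replicates were separate cultures. The authors deposited a non-normalized table of signal intensity, 1 column per array, exported with BeadStudio per the labels, whose version is not given in the sources used here. The authors also deposited processed log2 expression values, and against a quantile normalization of the intensity table on the log2 scale these differed by at most 0.0438. Both tables held 47231 probes, and all columns were mapped to a sample by the labels.

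The intensity table was the input. The planned background correction and filter needed detection p-values, which the table does not hold, so the fallback set in the design was used. Signals were taken as log2 with a floor at 16, which 0 values reached, and were quantile-normalized across the 18 arrays, after which every array had a median of 6.62. No background was subtracted, so fold changes of dim probes are understated. Probes above the array median on at least 3 arrays were kept, which left 32216 (68.2%). Of the 47231 probes 30113 carried 1 gene symbol, 8 several and 17110 none, and 30074 were found in the gene table by Entrez ID with 0 symbols changed. Of the tested probes 21612 carried 1 symbol. Chromosomes came from the gene table, and the genome build is not given in the sources used here.

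A linear model of the 6 group means was fitted with limma 3.58.1 in R 4.3.3, with 12 residual and 3.29 prior degrees of freedom. Moderated two-sided tests were made for 9 contrasts, which were Hec-1A against RL95-2 under control IgG, PDGF-AA against control IgG, PDGF-AA + 3G3 against PDGF-AA and PDGF-AA + 3G3 against control IgG in each line, and the differences between the lines in the PDGF-AA and 3G3 effects. P-values were adjusted by the Benjamini-Hochberg method over all tested probes of a contrast, with a threshold of 0.05. Between the lines, a gene whose group mean was at or below the array median was given a fold change with that group's arrays raised to at least the array median, as "at least". Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

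Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on the probe of highest mean per gene (15401 genes), adjusted over 27 lists written with the design and separately over 8 lists added after the data were seen. Camera with an estimated correlation and fry, which asks whether members move one way on balance, were run beside it. Members were counted by the adjusted p over all genes and adjusted over the list alone. Relations between effects were given as Pearson correlations and covariances across probes, beside 10000 simulations of unchanged groups that share the same arrays.

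Genes were named by a rule set with the design. Per pairwise comparison it took, among probes with 1 symbol, an adjusted p under the threshold and no overlap between the groups, the 10 largest fold changes each way. For the differences between lines it took the 5 largest each way. It added the PDGF family, the 4 members with the smallest p of each called list and of up to 6 other lists with called members, and, where none passed, the 5 smallest p-values each way. Non-overlap arises by chance in 10% of probes with 3 arrays against 3. Of genes with several probes the brightest was used. Some genes that the rule selects were left out of the text for length, as were unnamed transcripts.

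Alternatives were no normalization between arrays, scaling to a common median, normexp background correction with offsets of 16 and 50, the authors' processed values, no filter, a filter at the 75th percentile, an intensity trend with robust moderation, array weights, each cell line alone, a replicate block, a covariate, other thresholds, and leaving out each array or 4 arrays. For the 3 arrays against 3 all 10 splits were computed, and for the differences between lines 100 splits within each line. The models were tested on simulated data, where 50 probes changed 1.5-fold were called in 46 cases for PDGF-AA in Hec-1A, 39 for PDGF-AA in RL95-2, 44 for 3G3 in Hec-1A and 45 for 3G3 in RL95-2. Between 5 and 11 of the unchanged probes were called. With the changes added to the measured values 40, 39, 42 and 40 of the 50 were called in that order, along with 83, 20, 0 and 5 other probes. In each run 50 further probes each were changed 1.25-fold, 2-fold and 4-fold, which eases the adjusted threshold. The simulated noise was independent between probes, while 1 component held 61.3% of the measured residual variance in Hec-1A. The called shares therefore need not hold where few probes change. The number of arrays limits the precision of every value. The labels name no chip, so no chip effect was analysed here.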

Results

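Transcript levels were measured on 18 bead arrays of total RNA from 2 established human cell lines, Hec-1A, from an endometrial adenocarcinoma, and RL95-2, from an adenosquamous carcinoma of the endometrium. Each line was treated with control IgG, with PDGF-AA, a dimeric ligand of the platelet-derived growth factor receptor alpha, or with PDGF-AA plus 3G3, an antibody to that receptor, and each of the 6 groups held 3 arrays. The title of the series concerns blockade of this receptor in uterine cancer, and its design names the comparison of the lines. The replicates are not said to be separate cultures, so each p measures only the spread between these samples. The 75th percentile of signal per array ranged from 122.7 to 185.9, and single signals ranged from 66.7 to 22230. After filtering, 32216 of 47231 probes (68.2%) were tested in each comparison. The number of arrays limits the precision of every value, and the median 95% half-width was 0.155 for a log2 fold change between 2 groups. Values are log2 fold changes ± SE or normalized log2 signals ± SD, with n = 3 arrays per group except where arrays were left out. A change counts as passed at a limma adjusted p below 0.05 over all probes tested. Background remained in the signal, so the fold changes of dim probes are understated.

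The cell line separated the arrays. The leading principal component held 78.7% of the variance and the next 11.2%. The lowest correlation between arrays of the same line was 0.982 once Hec-1A control IgG replicate 1 was set aside, and the highest between lines was 0.93. Hec-1A control IgG replicate 1 stood apart from its own line, with correlations as low as 0.945. On that array, nuclear genes of the respiratory chain, a list written after the data were seen, lay at a median of -1.07 from the other Hec-1A control arrays. On the leading residual component of RL95-2, PDGF-AA replicate 1 and PDGF-AA + 3G3 replicates 2 and 3 scored 18.1, 23.6 and 20.2, while control IgG replicate 3 scored -20.9 and PDGF-AA + 3G3 replicate 1 scored -15.2. The first 3 of these and Hec-1A control IgG replicate 1 are the 4 arrays left out together in an alternative chosen after the data were seen. Without them the RL95-2 PDGF-AA + 3G3 group holds 1 array, replicate 1, so that alternative cannot test the 3G3 effect in RL95-2.

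**Figure D1:**
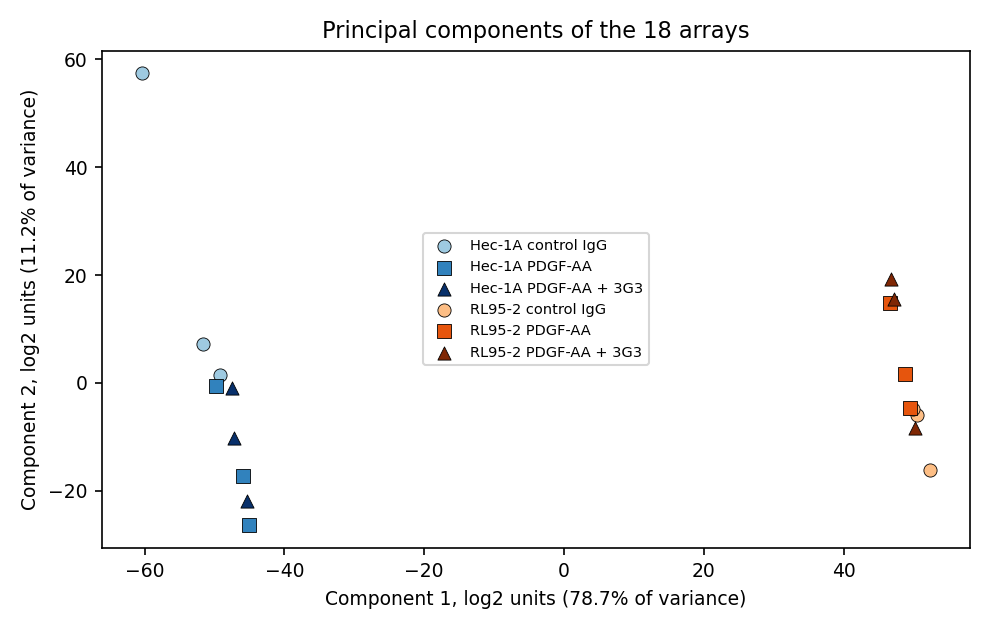
Scores of the 18 arrays on the leading principal components of normalized log2 signal, in log2 units, 1 point per array with colour for the line and shape for the treatment. Hec-1A lay at -60.41 to -45.05 and RL95-2 at 46.71 to 52.42 on component 1, and Hec-1A control IgG replicate 1 lay at 57.43 on component 2.

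The comparison of the lines under control IgG asks which transcripts differ between them without treatment. SPP1 (ILMN_1651354, chromosome 4), which encodes the secreted phosphoprotein osteopontin, was at least 103-fold higher in Hec-1A, at 13.33 ± 0.24 against 6.59 ± 0.09 in RL95-2 (adjusted p = 2.3e-14). The membrane protein TM4SF1 was higher by 5.86 and the receptor tyrosine kinase AXL by 5.08 ± 0.07 (adjusted p = 1.3e-17), and the matrix proteoglycan VCAN and the membrane peptidase DPP4 were at least 23.5-fold and 23.9-fold higher. TM4SF4, FXYD2 and SYT13, each at or below the array median on every RL95-2 control array, were at least 28.1-fold, 29.4-fold and 22-fold higher in Hec-1A. IGF2BP2, an RNA-binding protein, and AKR1C3, a reductase of steroids and prostaglandins, were higher by 4.33 and 4.26. RL95-2 had more of the calcium-binding partners S100A9 and S100A8, which were at least 133-fold and 46.8-fold lower in Hec-1A. S100A9 (ILMN_1750974, chromosome 1) lay at 6.45 ± 0.04 in Hec-1A and 13.68 ± 0.06 in RL95-2 (adjusted p = 1.7e-19). The imprinted noncoding RNA H19 and the serine synthesis enzyme PHGDH were at least 124-fold and 65.3-fold lower. The retinoic acid binding protein CRABP2 stood at -5.93, the siderophore-binding protein LCN2 at -5.76 and the transcriptional inhibitor ID3 at -5.47. CCND2, a cyclin of the G1 phase, was at least 42.6-fold lower. The respiratory chain gene UQCRH was at least 45.8-fold lower and its near-identical copy UQCRHL stood at -5.86, and whether the probes tell these copies apart was not tested.

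In limma, 11389 of the 32216 probes passed (35.4%), 5770 higher and 5619 lower in Hec-1A, where 13320 had an unadjusted p below 0.05 and chance gives 1611. They stood for 7447 genes, and 2544 probes differed at least 2-fold and 187 at least 8-fold. Without normalization between arrays the median of all probes moved to 0.11 and 68.1% of the calls were higher in Hec-1A, against 50.7% with it.

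Of 27 gene lists fixed before the data were examined, 9 differed between the lines in limma's camera test, which compares a list with all other genes. Cholesterol synthesis genes were higher in Hec-1A, with 14 of 17 members higher and 0 lower (median 1.41, adjusted p = 1.45e-07), including ACAT2 (3.67), MSMO1 (2.63), DHCR7 (2.04) and EBP (at least 8.44-fold). Output and feedback genes of the ERK pathway were higher, 12 of 17 against 4 lower (median 0.56, adjusted p = 0.017), with the phosphatase DUSP5 at 2.20 and the feedback inhibitor SPRY4 at 1.44, while PHLDA1 stood at -2.67 and the lipid kinase SPHK1 was at least 2.94-fold lower. Its adjusted p = 0.218 with an estimated correlation. Squamous markers were lower, 11 of 14 with 0 higher (median -0.74, adjusted p = 1.69e-05), among them the keratins KRT13 (-4.56) and KRT15 (-1.81), the desmosomal cadherin DSC3 (at least 2.91-fold) and TRIM29 (at least 2.92-fold). NF-kB inflammatory genes were lower, 14 of 18 with 1 higher (median -0.57, adjusted p = 8.36e-05), including the chemokines CXCL1 (-4.01) and CXCL2 (at least 4.54-fold) and the inhibitor NFKBIA (-2.68). The calls for cholesterol synthesis, squamous markers and NF-kB held with an estimated correlation, at adjusted p = 0.00109, 0.0333 and 0.0333.

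Antigen presentation genes were lower in Hec-1A in 12 of 18 members, with 0 higher (median -0.91, adjusted p = 5.67e-06, and adjusted p = 0.0664 with an estimated correlation). HLA-E stood at -3.15 and the peptide-loading protein TAPBP at -2.01, and HLA-B and HLA-F were at least 35.7-fold and 10.7-fold lower. Amino acid response genes were lower in 12 of 19 and higher in 2 (median -0.58, adjusted p = 0.000649, and adjusted p = 0.198 with an estimated correlation), with PHGDH, the amino acid transporter SLC7A5 (-3.02), the transcription factor CEBPB (-2.56) and the folate enzyme MTHFD2 (-1.45). Endoplasmic reticulum stress genes were lower in 9 of 16 and higher in 1 (median -0.51, adjusted p = 0.0188, and adjusted p = 0.124 with an estimated correlation), including XBP1 (-1.33) and the disulfide isomerase PDIA4 (-1.28). Angiogenic factors were lower in 8 of 17 and higher in 4 (median -0.29, adjusted p = 0.0188, and adjusted p = 0.0664 with an estimated correlation), with the vasodilator peptide ADM at -5.40 ± 0.12, the ephrins EFNA1 and EFNB2 at -2.22 and -1.62, and THBS1, an inhibitor of angiogenesis, at -1.91. Fibroblast and smooth muscle markers were lower in 6 of 14 and higher in 0 (median -0.13, adjusted p = 0.017, and adjusted p = 0.136 with an estimated correlation), among them COL5A1 (at least 2.42-fold), MYL9 (at least 2-fold) and FBLN1 (at least 28.3-fold). Adjusted over the list alone, 13 amino acid response genes, 11 endoplasmic reticulum stress genes and 9 angiogenic factors were lower, and the other counts of the 9 lists were the same.

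**Figure D2:**
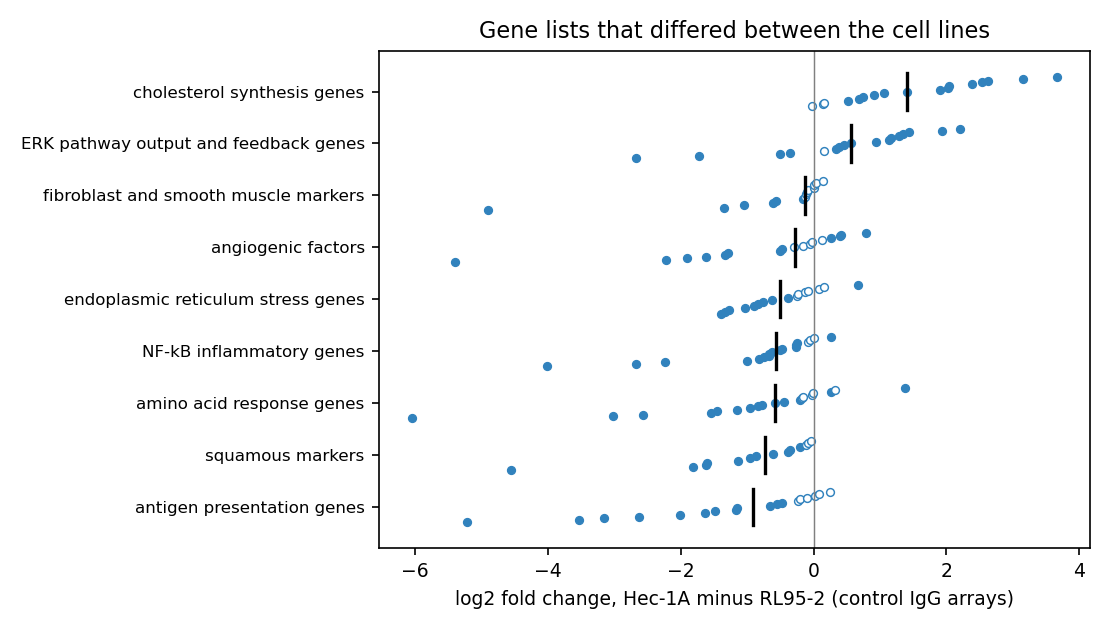
Log2 fold change of each tested member of the 9 gene lists that differed, Hec-1A minus RL95-2 on control IgG arrays (n = 3 each), 1 point per gene, filled where the gene passed and open where it did not, with a bar at the list's median. Medians ran from -0.91 for antigen presentation genes to 1.41 for cholesterol synthesis genes.

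The other 18 lists did not pass, although many of their members did. FOXO target genes were lower in 9 of 20 and higher in 2 (adjusted p = 0.0507), and this list was called, for 10 lists in all, without Hec-1A control IgG replicate 3 and without RL95-2 control IgG replicate 1 or 2. Of the receptor tyrosine kinases 9 of 18 were lower and 4 higher (adjusted p = 0.288), with FGFR3 at -2.46, EPHB4 at -1.33 and FGFR4 at 1.30 beside AXL. Epithelial markers were lower in 9 of 21 and higher in 5 (adjusted p = 0.179), including the cadherin CDH3 (at least 8.19-fold) and RAB25 (-2.32). Of the interferon response genes 9 of 23 were higher and 7 lower (adjusted p = 0.936), with BST2 at -4.43, IRF1 at -2.69 and IFIH1 at -1.63. Hypoxia response genes (8 higher, 5 lower of 19, adjusted p = 0.812) included DDIT4 at -2.72 and PFKFB4 at 1.63, and immediate early genes (7 higher, 6 lower of 22, adjusted p = 0.824) included EGR1 at 2.06 and KLF4 at -1.97. Cell cycle genes were higher in 9 of 35 and lower in 8 (adjusted p = 0.942), with CENPA at -1.36 and CDC6 at 0.45. The adjusted p was 0.142 for endometrial and hormone response genes, 0.634 for leukocyte and endothelial markers and for TGF-beta and SMAD target genes, 0.824 for glycolysis enzymes, heat shock genes and Wnt target genes, 0.854 for mesenchymal markers, 0.936 for p53 target genes and PI3K-AKT-mTOR components, and 0.964 for mismatch repair genes and the PDGF family. Median and mean differed in sign for interferon genes (0.01 and -0.20), receptor tyrosine kinases (-0.15 and 0.03), hypoxia genes (0.19 and -0.07), glycolysis enzymes (0.19 and -0.13), mesenchymal markers (-0.05 and 0.12), the TGF-beta list (0.08 and -0.08) and the PDGF family (0.02 and -0.09). The camera direction was down for the interferon, receptor and mesenchymal lists and up for the other 4. For p53 targets it was up with a median of -0.02 and a mean of -0.03, and for cell cycle genes it was up with a median of -0.002 and a mean of 0.03.

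Of the PDGF family, PDGFA, PDGFB and PDGFC differed between the lines, and PDGFD and PDGFRA did not pass. PDGFA (ILMN_2342695, chromosome 7) stood at -1.82 ± 0.07 (adjusted p = 8.9e-12), with 6.71 ± 0.12 in Hec-1A and 8.53 ± 0.10 in RL95-2. Of the dimmer PDGFA probes, ILMN_1685982 stood at -0.50 ± 0.06 (adjusted p = 1.2e-05). ILMN_1782661, near the array median in both lines, stood at -0.03 ± 0.06 and did not pass (adjusted p = 0.76). PDGFC (ILMN_1683023, chromosome 4) was higher in Hec-1A by 1.05 ± 0.13 (adjusted p = 9e-06), at 10.38 ± 0.35 against 9.33 ± 0.06, and PDGFB by 0.35 ± 0.08 (adjusted p = 0.0025). PDGFD differed by 0.02 (adjusted p = 0.83). PDGFRA, the receptor bound by PDGF-AA and 3G3 (ILMN_1681949, chromosome 4), lay near the array median of 6.62 in both lines, at 6.54 ± 0.02 in Hec-1A and 6.61 ± 0.04 in RL95-2 (-0.07 ± 0.05, adjusted p = 0.40). It was at or below the array median on every Hec-1A control array, and PDGFRB did not pass the filter. None of the 5 tested members passed in any treatment comparison in limma, where the largest of their fold changes was -0.30 ± 0.13 for PDGFC under PDGF-AA + 3G3 in Hec-1A (adjusted p = 0.21).

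**Figure D3:**
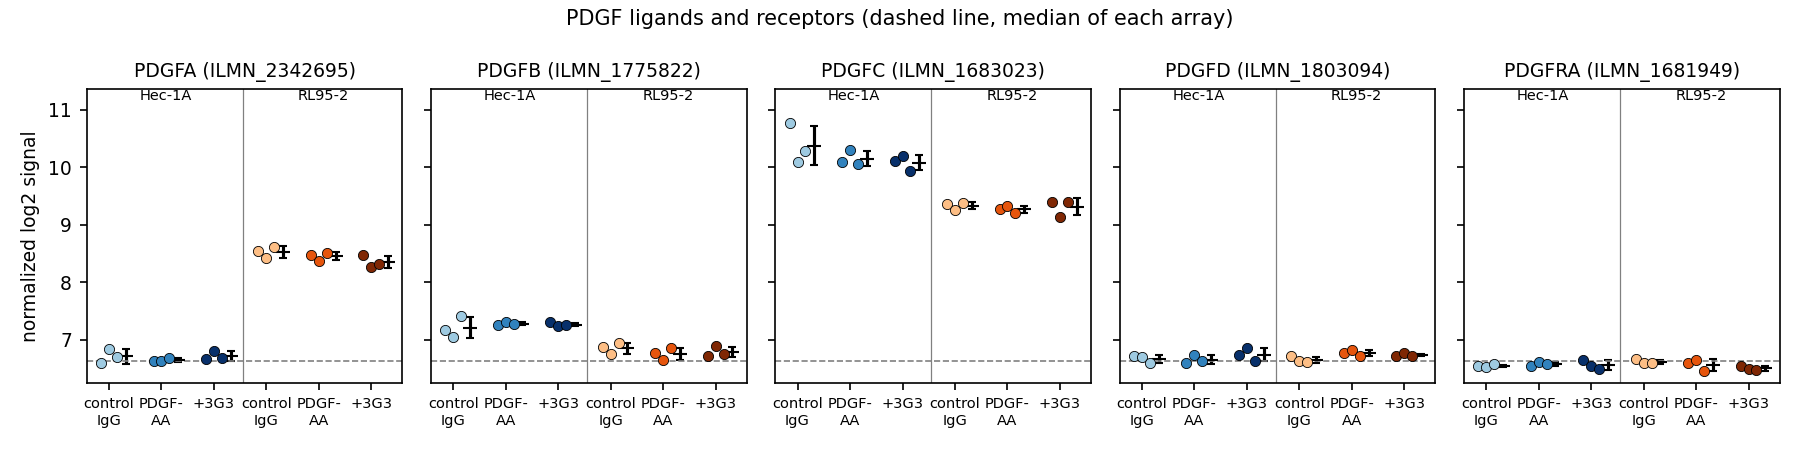
Normalized log2 signal of PDGFA, PDGFB, PDGFC, PDGFD and PDGFRA in the 6 groups, 1 point per array, with black bars for mean ± SD (n = 3) and a dashed line at the array median of 6.62. PDGFA in RL95-2 controls lay at 8.53 ± 0.10 and PDGFRA at 6.61 ± 0.04.

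PDGF-AA against control IgG asks which transcripts differed under the ligand. The labels name an antibody for the control group and none for the PDGF-AA group, so this comparison cannot tell ligand from antibody. In Hec-1A no transcript passed. The smallest p-values belonged to the actin-binding protein TAGLN (0.58 ± 0.09) and the phospholipase PLCB4 (-0.51 ± 0.07), both at adjusted p = 0.091. At an adjusted p of 0.11 stood GCN1 (0.47), ARHGAP1 (0.32), BRMS1 (0.52), BBLN (0.48), CLCC1 (-0.42), PNRC2 (-0.56), the isocitrate dehydrogenase IDH1 (-0.79 ± 0.16) and the interferon-induced gene IFIT1 (-0.79 ± 0.16). In limma 0 of 32216 probes passed while 6719 had an unadjusted p below 0.05, and this last count fell to 3002 without control IgG replicate 1, to 3753 without PDGF-AA replicate 1, and to 1497 with the component score as a covariate, where chance gives 1611. Without control IgG replicate 1 the count that passed stayed at 0. Without control IgG replicate 2 it was 3577, in a fit whose controls are replicate 3 and replicate 1, the array that stood apart. Without PDGF-AA replicate 2 it was 22. No list was called, and the smallest adjusted p was 0.401, for antigen presentation genes, epithelial markers and heat shock genes. Without normalization between arrays the median of all probes was -0.12.

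In RL95-2, TAGLN (ILMN_1778668, chromosome 11), an actin-binding protein of smooth muscle, was lower under PDGF-AA. It fell by 0.67 on the log2 scale from 7.80 ± 0.07 to 7.14 ± 0.02 (SE 0.09, adjusted p = 0.016). PLAC8 (ILMN_1653026, chromosome 4), named because it was the other of the 2 probes that passed and chosen after its values were seen, fell by 0.70 from 10.55 ± 0.11 to 9.85 ± 0.09 (adjusted p = 0.016). The brighter PLAC8 probe had -0.45 ± 0.07 (adjusted p = 0.059). Mesenchymal markers were lower as a list, with 12 of 14 members negative (median -0.13, adjusted p = 0.000418), and this call held with an estimated correlation (adjusted p = 0.0222). Its smallest p-values belonged to the transcription factors TWIST2 (-0.35), TWIST1 (-0.21) and SNAI2 (-0.22) and to GNG11 (-0.18). Amino acid response genes were lower, with 17 of 19 negative (median -0.14, adjusted p = 5.28e-05, and adjusted p = 0.266 with an estimated correlation), including asparagine synthetase ASNS (-0.55) and the serine synthesis enzymes PHGDH (-0.40) and PSAT1 (-0.29). Heat shock genes were higher, with 12 of 14 positive (median 0.10, adjusted p = 0.0314, and adjusted p = 0.306 with an estimated correlation), including the chaperone HSPA8 (0.46), with its cochaperone BAG3 at -0.16. In these 3 lists 0 members passed over all genes, and adjusted over the list alone 5 amino acid response genes, 1 mesenchymal marker and 0 heat shock genes did. Fibroblast and smooth muscle markers, which include TAGLN, were not called (adjusted p = 0.165).

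In limma 2 probes passed, both lower, while 1832 had an unadjusted p below 0.05 and 1150 without PDGF-AA replicate 1. Leaving out any of the 6 arrays ended the TAGLN call, at an adjusted p of 0.062, 0.098 and 0.14 without control IgG replicates 1, 2 and 3, and of 0.14, 0.076 and 0.081 without PDGF-AA replicates 1, 2 and 3. For PLAC8 these values were 0.062, 0.064, 0.14, 0.14, 0.076 and 0.054 in the same order. Over 19 alternatives the adjusted p ranged from 0.0019 to 0.41 for TAGLN and from 0.0056 to 1 for PLAC8. The heat shock call ended with scaling to a common median (adjusted p = 0.399), and without control IgG replicate 3 (0.162), PDGF-AA replicate 2 (0.0507) or PDGF-AA replicate 3 (0.182), over a range of 0.000841 to 0.399.

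**Figure D4:**
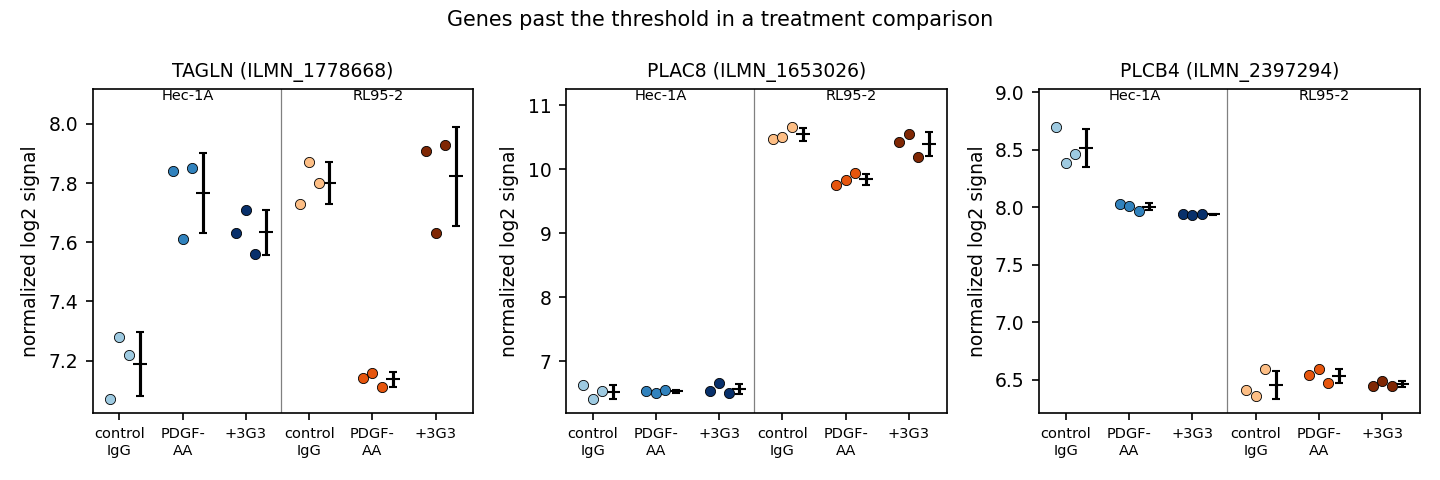
Normalized log2 signal of TAGLN, PLAC8 and PLCB4 in the 6 groups, 1 point per array, with black bars for mean ± SD (n = 3) and a separate vertical scale per gene. In RL95-2, TAGLN lay at 7.80 ± 0.07 under control IgG, 7.14 ± 0.02 under PDGF-AA and 7.83 ± 0.17 under PDGF-AA + 3G3.

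PDGF-AA + 3G3 against PDGF-AA asks what differed when the antibody was added to the ligand. No group is labelled PDGF-AA with control IgG, so 3G3 cannot be told from the presence of any antibody. In Hec-1A the smallest p-values belonged to the import receptor TNPO3 (-0.26), the kinase NEK6 (-0.27) and the serpin SERPINC1 (-0.22), all at an adjusted p of 1. DALRD3 (0.34) and the flavoprotein ETFDH (0.32) also stood at 1. Hypoxia response genes were higher as a list, with 17 of 19 positive (median 0.07, adjusted p = 0.0281, and adjusted p = 0.299 with an estimated correlation), including NDRG1 (0.28), BNIP3 (0.26) and ADM (0.25). Of its members 0 passed over all genes and 0 adjusted over the list alone. In limma 0 probes passed and 1312 had an unadjusted p below 0.05. The hypoxia call ended without PDGF-AA replicate 2 (0.0574), PDGF-AA replicate 3 (0.0988), PDGF-AA + 3G3 replicate 1 (0.283) or PDGF-AA + 3G3 replicate 2 (0.066), over a range of 0.00045 to 0.471. NF-kB genes were also called without PDGF-AA replicate 1, and glycolysis enzymes without PDGF-AA + 3G3 replicate 3, for 2 lists each.

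In RL95-2, TAGLN rose by 0.69 ± 0.09 when 3G3 was added to PDGF-AA, from 7.14 ± 0.02 to 7.83 ± 0.17 (adjusted p = 0.021). Its level under control IgG was 7.80 ± 0.07. Both PLAC8 probes were higher, ILMN_2093343 by 0.43 ± 0.07 and ILMN_1653026 by 0.55 ± 0.09, and did not pass (adjusted p = 0.15 each). Interferon response genes were higher as a list, with 16 of 23 positive (median 0.09, adjusted p = 0.00656), and this call held with an estimated correlation (adjusted p = 0.0432). Its smallest p-values belonged to the antiviral membrane protein BST2 (0.14), the transcription factor IRF9 (0.12) and IFIT3 (0.20), and 0 members passed over all genes or adjusted over the list alone. In limma 1 probe passed and 1040 had an unadjusted p below 0.05, or 1671 without PDGF-AA replicate 1 and 2074 without PDGF-AA + 3G3 replicate 1, and 2 passed without PDGF-AA + 3G3 replicate 3. The TAGLN call ended without PDGF-AA replicates 1, 2 or 3 (adjusted p of 0.15, 0.16 and 0.22) and without PDGF-AA + 3G3 replicates 1 or 3 (0.23 and 0.085), and the range over 19 alternatives was 0.00048 to 0.72. The interferon call ended without PDGF-AA + 3G3 replicate 1 (adjusted p = 0.0841), over a range of 0.000318 to 0.0841. Counts of 2 lists came from immediate early genes without PDGF-AA replicate 1 and from amino acid response genes without PDGF-AA replicate 3 or PDGF-AA + 3G3 replicate 3.

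Ligand plus antibody was also compared with control IgG. In Hec-1A, PLCB4 (ILMN_2397294, chromosome 20), a phospholipase that signals downstream of G proteins, fell by 0.58 from 8.51 ± 0.17 to 7.94 ± 0.01 (SE 0.07, adjusted p = 0.030). PDGF-AA alone already gave -0.51 ± 0.07 for this probe, and adding 3G3 to PDGF-AA gave -0.07 ± 0.07. A dimmer PLCB4 probe fell by 0.27 and did not pass (adjusted p = 0.084). In limma ILMN_2397294 was the only probe to pass, with 6563 at an unadjusted p below 0.05. That last count became 3386 without control IgG replicate 1 and 2253 with the component score as a covariate. The PLCB4 call ended without control IgG replicate 3 (adjusted p = 0.078) and without PDGF-AA + 3G3 replicates 1, 2 or 3 (0.079, 0.14 and 0.13), over a range of 0.00069 to 0.37. Without control IgG replicate 2 the count of probes was 3847, in a fit whose controls are replicate 3 and replicate 1, which stood apart. In RL95-2 none passed, and the smallest adjusted p was 0.23, for the carboxypeptidase CPA4 (0.43), the membrane flippase ATP8B1 (-0.40) and MXRA7 (-0.35), followed by the steroid dehydrogenase HSD17B2 (0.33) at 0.24. There limma gave 0 probes, with 3025 at an unadjusted p below 0.05. This last count was 1670 without control IgG replicate 3, 1579 without PDGF-AA + 3G3 replicate 2, 1781 without PDGF-AA + 3G3 replicate 3 and 5044 without PDGF-AA + 3G3 replicate 1. Without the last of these 26 probes passed, and 1 passed without control IgG replicate 2. No list was called in either line by camera, which called cell cycle genes in Hec-1A without control IgG replicate 1, amino acid response genes in RL95-2 without control IgG replicate 2, and immediate early, ERK pathway and mesenchymal lists in RL95-2 without PDGF-AA + 3G3 replicate 3.

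The effects in the lines were compared directly through the difference of their fold changes, Hec-1A minus RL95-2. For PDGF-AA, TAGLN differed by 1.24 ± 0.12 (adjusted p = 0.00088), from 0.58 ± 0.09 in Hec-1A, which did not pass, and -0.67 ± 0.09 in RL95-2. It passed in 22 of 24 alternatives, over a range of 4e-05 to 0.17. Of the other 2, a replicate block gave 0.073, and no normalization between arrays gave 0.17 and moved the median of all probes to -0.14. In limma 1 probe passed with 6364 at an unadjusted p below 0.05, which became 2036 with the component score as a covariate. Without Hec-1A control IgG replicate 2 there were 2152 that passed, 3 without Hec-1A control IgG replicate 3 and 7 without Hec-1A PDGF-AA replicate 2. The first of these fits keeps replicate 1, which stood apart, and replicate 3 as the Hec-1A controls. No list was called, and heat shock genes were called without RL95-2 PDGF-AA replicate 1.

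For 3G3, no gene passed the test of the difference. The smallest p belonged to TAGLN (-0.82 ± 0.12, adjusted p = 0.17). The vasoconstrictor peptide EDN1 (0.40 ± 0.11) and the brighter PLAC8 probe (ILMN_2093343, -0.46 ± 0.10) stood at an adjusted p of 1. The PLAC8 probe that passed for PDGF-AA in RL95-2 (ILMN_1653026) gave -0.51 ± 0.12 here and did not pass. In limma 0 probes passed, 907 had an unadjusted p below 0.05, and 1 passed without RL95-2 PDGF-AA + 3G3 replicate 2. NF-kB inflammatory genes were higher in Hec-1A relative to RL95-2, with 13 of 18 positive (median 0.13, adjusted p = 0.00925), with CXCL2 at 0.27 and CCL20 at 0.28. So were hypoxia response genes, with 15 of 19 (median 0.06, adjusted p = 0.016) and NDRG1 at 0.44, immediate early genes, with 16 of 22 (median 0.08, adjusted p = 0.0192), EGR1 at 0.28 and FOS at 0.18, and angiogenic factors, with 12 of 17 (median 0.07, adjusted p = 0.046). Mesenchymal markers were lower, with 11 of 14 negative (median -0.09, adjusted p = 0.00647), among them the integrin ITGA5 (-0.24), the cadherin CDH2 (-0.21) and AXL (-0.20). None of the 5 held with an estimated correlation, where the adjusted p = 0.136, 0.276, 0.56, 0.136 and 0.0564 in that order. Over all genes 0 members passed, and adjusted over the list alone 1 angiogenic factor, EDN1, did.

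These list differences for 3G3 depended on single arrays. The NF-kB call ended without Hec-1A PDGF-AA replicate 2 (adjusted p = 0.085), RL95-2 PDGF-AA replicate 2 (0.0507) or RL95-2 PDGF-AA + 3G3 replicate 1 (0.0661), over a range of 0.004 to 0.314. The hypoxia call ended without Hec-1A PDGF-AA replicate 3 (0.0643), Hec-1A PDGF-AA + 3G3 replicate 1 (0.213) or RL95-2 PDGF-AA replicate 2 (0.0507), over 0.00403 to 0.624. The immediate early call ended without Hec-1A PDGF-AA replicates 2 or 3 (0.0751 and 0.072), Hec-1A PDGF-AA + 3G3 replicate 2 (0.216), RL95-2 PDGF-AA replicates 2 or 3 (0.0832 and 0.126) or RL95-2 PDGF-AA + 3G3 replicate 2 (0.223), over 0.00407 to 0.767. The angiogenic call ended without Hec-1A PDGF-AA replicates 2 or 3 (0.0667 and 0.207), Hec-1A PDGF-AA + 3G3 replicates 1 or 2 (0.107 and 0.188), RL95-2 PDGF-AA replicates 1, 2 or 3 (0.0734, 0.0899 and 0.0636) or RL95-2 PDGF-AA + 3G3 replicates 1 or 2 (0.123 and 0.147), over 0.0104 to 0.281. The mesenchymal call held without any single array, with a lowest adjusted p of 0.0014, and ended with an estimated correlation and with fry. Without the 4 arrays left out together RL95-2 holds 1 PDGF-AA + 3G3 array, so that fit cannot decide the call. Amino acid response genes were called without RL95-2 PDGF-AA replicate 3 (4 lists in all) or RL95-2 PDGF-AA + 3G3 replicate 3 (6 lists in all).

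Whether 3G3 turned back the changes under PDGF-AA was examined across all 32216 probes, which are not independent replicates. Both effects use the PDGF-AA arrays, which alone makes their correlation negative, and 10000 simulations without any effect gave a median r of -0.578 in Hec-1A (95% range -0.961 to 0.621) and -0.55 in RL95-2 (-0.949 to 0.56). The measured r was -0.272 in Hec-1A, and without a single array it ranged from -0.584 (PDGF-AA replicate 2) to -0.002 (PDGF-AA replicate 1). It was 0.031 in RL95-2, with a range of -0.256 (PDGF-AA + 3G3 replicate 2) to 0.324 (PDGF-AA + 3G3 replicate 1). The covariance was -0.00565 and 0.000313 against simulated means of -0.00787 and -0.00459. TAGLN in RL95-2 was the 1 probe that passed in both comparisons with opposite signs. The PDGF-AA effect correlated with that of PDGF-AA + 3G3 at r = 0.902 in Hec-1A and 0.792 in RL95-2, where simulated groups sharing the control arrays gave medians of 0.578 and 0.566 and 95% ranges of -0.625 to 0.963 and -0.558 to 0.952, which hold both measured values. Between the lines, which share no arrays, r was -0.557 for PDGF-AA, where 95% of simulated values lay between -0.538 and 0.547, and 0.348 for 3G3, where they lay between -0.541 and 0.544. Without RL95-2 PDGF-AA replicate 1 the first was -0.393, inside the simulated range, and without Hec-1A PDGF-AA + 3G3 replicate 3 the other was 0.145. With the score of the leading residual component as a covariate, chosen after the data were seen, r for PDGF-AA between the lines was -0.075 and that between the PDGF-AA and 3G3 effects in RL95-2 was -0.41.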

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

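The test of the residual component shared with RL95-2, and the model with a component score as covariate, were chosen after the results were seen. A difference between the cell lines in an effect of treatment was found for 6 results by a test of that difference. TAGLN differed by 1.24 in its PDGF-AA effect. The other 5 were list calls for the 3G3 effect, and none of them held with an estimated correlation. The camera adjusted p was 0.0192 for immediate early genes (adjusted p = 0.56 with an estimated correlation), 0.046 for angiogenic factors (0.136), 0.016 for hypoxia response genes (0.276), 0.00925 for NF-kB inflammatory genes (0.136) and 0.00647 for mesenchymal markers (0.0564).

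TAGLN fell under PDGF-AA in RL95-2 and rose when 3G3 was added. In that line it was low only in the group whose label names no antibody, and the design cannot tell ligand from antibody there. Cells of a fibroblast or smooth muscle type in some arrays stay open. The median fold change of 13 other markers was -0.029, past the bound set beforehand for excluding such cells, but that bound was wrong, because 10 of the 13 lay less than 2-fold above the array median in RL95-2 controls. The 3 brighter markers had a median of -0.222, with ACTA2 at -0.24 ± 0.10, COL5A1 at -0.22 and FBLN1 at -0.08. When 3G3 was added they stood at 0.08, -0.01 and -0.05 in that order, where TAGLN rose by 0.69, which goes against such cells for the rise but does not exclude them, since RL95-2 controls already carry these 3 markers at 7.90 to 11.45. With the component score as a covariate TAGLN still stood at -0.64 (adjusted p = 0.0044, over a range of 0.0019 to 0.41), which argues against that component as the cause. A fault of 1 probe stays open, since another TAGLN probe gave -0.105, short of the fall of 0.3 set beforehand. That probe went the same way as the main one for 3G3 in RL95-2 (0.15 ± 0.05) and for the PDGF-AA difference (0.26 ± 0.07). It was dim, with group means of 6.65 to 6.8 in RL95-2. A further TAGLN probe, at 6.55 ± 0.14 in RL95-2 controls, gave -0.01 ± 0.06 for PDGF-AA and 0.09 ± 0.06 for 3G3 in RL95-2. For the PDGF-AA difference it gave -0.01 ± 0.09. Probes this near the array median cannot decide whether the main probe was at fault. A change of actin cytoskeleton genes driven by SRF and MRTF also stays open, with a camera p of 0.0505 for that list without TAGLN, and the bound set beforehand for excluding it was wrong, since a p over the threshold excludes nothing. This bound and that for the markers were set aside after the values were known.

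Hec-1A control IgG replicate 1 stood apart from the other Hec-1A arrays, with 521 probes higher and 332 lower by over 1 on the log2 scale (2.65% of those tested). RNA of RL95-2 in that array is argued against, because 323 probes at least 4-fold higher in RL95-2 deviated by a median of -0.029 where their difference between the lines was 2.66. Brightness explained a share of 0.013 of the variance of that array's deviation after quantile normalization. That step evens out a signal scale that differs with brightness, so the test cannot decide whether the array had one. The deviation correlated at r = 0.402 across probes with the component that separates arrays of the same group in RL95-2, so the arrays of both lines may share a source of variation, which was not identified. A trend with genomic gene length (Spearman rho 0.291) stays open, and no biological explanation was tested.

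Other splits of the same arrays were computed for each comparison, and for 3 arrays against 3 the 10 splits are too few for a share under 0.05. Between the lines the real split gave 11389 probes and 9 lists and the highest other 0 and 6, with 1 split as large for each. PDGF-AA gave 0 probes in Hec-1A with a highest other of 0 (10 splits as large), and 0 lists against 0 (10 splits). In RL95-2 it gave 2 probes against 0 and 3 lists against 2 (1 split each). Adding 3G3 in Hec-1A gave 0 probes against 5 (10 splits) and 1 list against 2 (3 splits). In RL95-2 it gave 1 probe against 263 (2 splits) and 1 list against 2 (4 splits). The split with 263 probes set PDGF-AA replicate 1 with PDGF-AA + 3G3 replicates 2 and 3, which points to a structure of these samples other than treatment. PDGF-AA + 3G3 against control IgG gave 1 probe against 0 (1 split) and 0 lists against 2 (10 splits) in Hec-1A, and 0 probes against 0 and 0 lists against 2 (10 splits each) in RL95-2.

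For the differences between lines 100 splits were drawn. The PDGF-AA difference gave 1 probe against a highest other of 0, with 1 of 100 splits as large, and 0 lists against 4 (100 of 100 splits). Chance is unlikely for that count of 1 probe but is not excluded, since the split tests were not adjusted for their number. The 3G3 difference gave 5 lists against 4, with 1 of 100 splits as large. A margin of 1 list does not exclude chance, and the count was 0 with an estimated correlation, 0 with fry and 1 without RL95-2 PDGF-AA replicate 2. For probes the 3G3 difference gave 0 against 2313 (100 of 100 splits). The split with 2313 probes again points to a structure of the samples.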

How the results depend on the processing

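The normexp offsets of 16 and 50, the 75th percentile filter, the covariate and the tests without 4 arrays, as well as the list tests without Hec-1A control IgG replicate 1, were chosen after the data were seen. Of the gene and gene list results 4278 kept their direction and their side of the threshold, 102 no longer passed, 41 newly passed, 69 moved and 0 reversed. For the 82 genes named between the lines 1550 of 1555 values kept both. Genes that passed in neither fit count as kept, and alternatives such as no filter leave the fold change unchanged. The counts of kept results therefore do not measure how well calls held. The treatment calls held less often. In RL95-2, TAGLN passed in 10 of 19 alternatives for PDGF-AA and PLAC8 in 8 of 19. For 3G3 there TAGLN passed in 10 of 19, counting the fit without 4 arrays. PLCB4 passed in 7 of 19 for PDGF-AA + 3G3 in Hec-1A, and TAGLN in 22 of 24 for the PDGF-AA difference. Background was not subtracted, so signal near it limits the fold changes of dim genes, and the cause of the changes listed here was not tested. A chip block, a filter on detection p under 0.01, and opposition among probes called under PDGF-AA (0 and 2 probes) were planned and not run, since the files name no chip and hold no detection p, and the probes were too few.

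The count for PDGF-AA in RL95-2 was 0 without normalization, 1 with scaling to a common median, 1 with normexp offset 16, 4 with an intensity trend, 9 with array weights, 0 with each cell line alone, 6 with the component score as a covariate and 0 at an adjusted p under 0.01. Without the 4 arrays RL95-2 holds 1 PDGF-AA + 3G3 array, and TAGLN stood at 0.763 for 3G3 there. The count for 3G3 in RL95-2 was 0 without normalization, 0 with each cell line alone, 2 with the covariate and 0 at the stricter threshold. For PDGF-AA + 3G3 in Hec-1A it was 0 without normalization, with scaling to a common median, with normexp offset 16 or 50, with each line alone, with the covariate, without the 4 arrays, with a fold of at least 1.5 and at the stricter threshold, 1143 with the 75th percentile filter, 281 with an intensity trend and 3714 with array weights. PDGF-AA in Hec-1A gave 2 with an intensity trend and 4622 with array weights, and PDGF-AA + 3G3 in RL95-2 gave 36 with array weights. The PDGF-AA difference between the lines gave 0 without normalization and 2571 with array weights. The 3G3 difference gave 1 with scaling to a common median, with array weights and with the covariate. Array weights were 0.2 for Hec-1A control IgG replicate 1 and 6.68 for replicate 3. The line comparison gave 5530 with a fold of at least 1.5.

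With a replicate block the counts were 0 for PDGF-AA in RL95-2, 3G3 in RL95-2, PDGF-AA + 3G3 in Hec-1A and the PDGF-AA difference, and 10990 between the lines. With it the adjusted p of TAGLN was 0.35 for PDGF-AA in RL95-2, 0.72 for 3G3 in RL95-2 and 0.073 for the PDGF-AA difference, over ranges of 0.0019 to 0.41, 0.00048 to 0.72 and 4e-05 to 0.17. Residuals of arrays with the same number correlated at a mean of -0.187 in Hec-1A (-0.505 to 0.155) and -0.145 in RL95-2 (-0.701 to 0.331). These values give no sign that the numbers paired samples, but with so few arrays they cannot exclude it.

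With an estimated correlation 3 lists were called between the lines, 1 for PDGF-AA in RL95-2, 0 for 3G3 in Hec-1A and 0 for the 3G3 difference. Fry called 18 between the lines, 0 for 3G3 in Hec-1A, 0 for 3G3 in RL95-2, 3 for PDGF-AA + 3G3 in Hec-1A and 1 in RL95-2, 2 for the PDGF-AA difference and 0 for the 3G3 difference. For PDGF-AA in RL95-2 fry called 2 lists, of which 1 was shared with the main test. Scaling to a common median gave 4 lists there, of which 2 were shared, 2 for 3G3 in RL95-2 and 3 for PDGF-AA + 3G3 in Hec-1A. The covariate gave 4 for PDGF-AA in Hec-1A, 5 in RL95-2, 4 for 3G3 in Hec-1A, 2 in RL95-2 and 2 for PDGF-AA + 3G3 in Hec-1A. Without the 4 arrays there were 5 lists for PDGF-AA in RL95-2 and 1 for the PDGF-AA difference. Counts for 3G3 in RL95-2 and for the 3G3 difference are left out, since 1 RL95-2 PDGF-AA + 3G3 array remains. With the covariate the correlation of the PDGF-AA and 3G3 effects in RL95-2 was -0.41 and that of the PDGF-AA effects between the lines -0.075.

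Leaving out each array in turn, the probe count ranged from 9824 (without RL95-2 control IgG replicate 3) to 11482 (without Hec-1A control IgG replicate 2) between the lines. It ranged from 0 to 3577 (without control IgG replicate 2) for PDGF-AA in Hec-1A, 0 to 1 (without control IgG replicate 2) for PDGF-AA in RL95-2, 0 to 2 (without PDGF-AA + 3G3 replicate 3) for 3G3 in RL95-2, 0 (without control IgG replicate 3) to 3847 (without control IgG replicate 2) for PDGF-AA + 3G3 in Hec-1A and 0 to 26 (without PDGF-AA + 3G3 replicate 1) in RL95-2. It ranged from 1 to 2152 (without Hec-1A control IgG replicate 2) for the PDGF-AA difference and 0 to 1 (without RL95-2 PDGF-AA + 3G3 replicate 2) for the 3G3 difference. Leaving out Hec-1A control IgG replicate 2 keeps replicate 1, which stood apart, and replicate 3 as the Hec-1A controls. List counts ranged from 9 to 10 between the lines, 2 to 3 for PDGF-AA in RL95-2, 0 (without PDGF-AA replicate 2) to 2 (without PDGF-AA replicate 1) for 3G3 in Hec-1A and 0 (without PDGF-AA + 3G3 replicate 1) to 2 (without PDGF-AA replicate 1) in RL95-2. They ranged from 0 to 1 (without control IgG replicate 1) for PDGF-AA + 3G3 in Hec-1A, 0 to 3 (without PDGF-AA + 3G3 replicate 3) in RL95-2, 0 to 1 (without RL95-2 PDGF-AA replicate 1) for the PDGF-AA difference and 1 (without RL95-2 PDGF-AA replicate 2) to 6 (without RL95-2 PDGF-AA + 3G3 replicate 3) for the 3G3 difference. The correlation of the PDGF-AA and 3G3 effects ranged from -0.584 (without PDGF-AA replicate 2) to -0.002 (without PDGF-AA replicate 1) in Hec-1A and from -0.256 (without PDGF-AA + 3G3 replicate 2) to 0.324 (without PDGF-AA + 3G3 replicate 1) in RL95-2. Between the lines it ranged from -0.606 to -0.393 for PDGF-AA and from 0.145 (without Hec-1A PDGF-AA + 3G3 replicate 3) to 0.468 (without RL95-2 PDGF-AA + 3G3 replicate 1) for 3G3.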

Other observations

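The 8 gene lists and the tests of this part were chosen after the data were seen, and the genes named were chosen after their values were seen. Hec-1A had less of the developmental HOX transcription factors than RL95-2, with 11 of 22 tested members lower and 1 higher (13 and 1 adjusted over the list alone; adjusted p = 0.000944 in limma's camera over the added lists, and adjusted p = 0.109 with an estimated correlation). HOXC13 stood at -2.37, HOXD11 at -1.61 and HOXB5 at -1.22, and HOXD13 and HOXC8 were at least 2.25-fold and 2.11-fold lower, while HOXA2 was higher at 2.11. Integrins and laminins, which bind cells to the basement membrane, were higher in 9 and lower in 4 of 15 (adjusted p = 0.0707), with LAMB3 at 2.05, ITGA3 at 1.20, ITGB3 at least 3.7-fold higher, and LAMB1 at -1.16. Mucin and secretory genes were lower in 6 and higher in 2 of 13 (adjusted p = 0.0747), with SLPI at -2.40, AGR2 at least 4.7-fold lower and MUC4 at least 1.82-fold higher. Xenobiotic and glutathione genes were higher in 9 and lower in 5 of 18 (adjusted p = 0.198), with TXNRD1 at 2.25 and ABCC3 at 2.04 against HMOX1 at -1.32 and NQO1 at -0.94. Cancer-testis antigen genes were higher in 2 of 10 (adjusted p = 0.198), among them PRAME (0.94), and SRF-MRTF cytoskeleton genes were higher in 5 and lower in 5 of 18 (adjusted p = 0.411). Nuclear genes of the respiratory chain were lower in 18 of 30 (median -0.81, adjusted p = 0.000944, and 0.498 with an estimated correlation), and ribosomal protein genes were lower in 12 and higher in 1 of 30 (adjusted p = 0.0747).

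Among the treatment comparisons, respiratory chain genes were higher in Hec-1A under PDGF-AA (24 of 30 positive, median 0.50, adjusted p = 1.12e-05, and 0.667 with an estimated correlation) and under PDGF-AA + 3G3 (30 of 30, median 0.52, adjusted p = 9.33e-10, and 0.419 with an estimated correlation). Ribosomal protein genes were higher in the same comparisons (adjusted p = 0.0125 and 8e-04, and 0.667 and 0.419 with an estimated correlation), and integrin and laminin genes were lower under PDGF-AA + 3G3 (12 of 15 negative, adjusted p = 0.0187, and 0.419 with an estimated correlation). All of these use Hec-1A control IgG replicate 1, on which respiratory chain genes deviated by a median of -1.07 with 28 of 30 below 0, ribosomal protein genes by -0.43 and integrin and laminin genes by 0.46. They may therefore stand for that array rather than for treatment, and the component shared with RL95-2 correlated with its deviation at r = 0.402. These added lists were not tested without that array. Respiratory chain genes were also called when 3G3 was added in Hec-1A (adjusted p = 0.0207, and 0.666 with an estimated correlation) and for the PDGF-AA difference between the lines (adjusted p = 0.0134, and 0.737 with an estimated correlation). HOX genes were lower in RL95-2 under PDGF-AA + 3G3 (19 of 22 negative, median -0.12, adjusted p = 0.000302, and 0.0568 with an estimated correlation) and under PDGF-AA (17 of 22, adjusted p = 0.0444, and 0.399 with an estimated correlation), and differed between the lines for 3G3 (18 of 22 positive, adjusted p = 0.0197, and 0.278 with an estimated correlation). In no treatment comparison did a member of these lists pass over all genes in limma.

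On Hec-1A control IgG replicate 1 the probes farthest above the other control arrays belonged to the integrin ITGAV (2.34), the adaptor CD2AP (2.28), the nuclear export receptor XPO1 (2.22) and the helicase HLTF (2.22), and that farthest below to FXYD2 (-1.72). The leading residual component held 61.3% of the residual variance in Hec-1A and 54.6% in RL95-2.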
